A study of Mus musculus with 52 samples.

How the data were processed

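RNA was measured in 52 tumours in 6 groups given by age (young or aged) and antibody (isotype, anti-PD-L1 or anti-CTLA4). Per the labels' protocols, Balb/C mice received 100000 4T1 cells in the 4th left mammary fat pad and 3 intraperitoneal doses of antibody, namely clone 9D9 against CTLA4, clone 10F.9G2 against PD-L1 or the isotype clone LTF-2, and tumours were taken at no more than about 150 mm3. Libraries of total RNA were made with a strand-marking poly(A) kit from 500 ng, and paired reads of 75 bases were sequenced on a NextSeq500 in 3 batches that the labels number.

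The submitters' processing notes name Salmon, DESeq2 1.16.1 and the mouse build mm10, and no version of Salmon. The authors deposited a table of estimated counts per gene, all of them whole numbers, and a table of TPM values of the same libraries, with Ensembl gene identifiers. The whole-number counts were in proportion to the deposited TPM times a length per gene that was common to the libraries, with a largest log2 deviation of 0.0021 over 2641 genes with at least 500 counts in each library, as estimated counts scaled by length are. TPM values were used for this check and for the effective gene length alone. How Salmon's transcript estimates were summed to genes, and whether its estimates used strand, is not given in the sources used here, so reads of paralogs, overlapping genes and antisense genes are uncertain. Of 47729 identifiers, 47224 matched a symbol in GENCODE vM21 (GRCm38), 505 did not, and 11075 were 0 in every library.

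TMM factors ran from 0.618 to 1.21, and the 10 most counted genes took 5.56 to 11.2% of a library. Libraries of a group were compared pairwise for copies. The smallest chi-square per degree of freedom of 209 pairs was 24.7, above sampling noise. This cannot show a tumour prepared again in another batch. Each library counted as 1 replicate.

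Genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with filterByExpr (17899 genes kept), TMM factors, 1 fit over all libraries with terms for group and sequencing batch, and quasi-likelihood F tests. The 11 comparisons were anti-PD-L1 and anti-CTLA4 each against isotype within an age, aged against young within an antibody, the difference of each antibody effect between ages, and anti-CTLA4 against anti-PD-L1 within an age. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and log2 fold changes are given with their SE. CPM values are TMM-normalized, and log2 CPM used a prior count of 2.

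The lists of genes, 33 in all with 622 genes of pathways and cell types, of which 3 matched no symbol, were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison, beside an estimated correlation. Lists with under 5 tested members were not tested. A list's median is that of its members' log2 fold changes. A list's level is the mean log2 CPM of its members in a library. The design, lists and rule for named genes were fixed before the data were examined. The rule took, per comparison, the 10 higher and 10 lower passing genes of smallest p with a mean of at least 1 CPM and no predicted model, up to 4 genes of smallest p per list that passed or held a passing gene, and a fixed set of immune genes, among them Cd274, Ctla4, Pdcd1, Ifng, Cxcl9, Cd8a and Foxp3, in antibody comparisons; 2 genes that the rule took are not reported here, for reasons other than their values. Where under 5 genes passed, it took the 3 genes of smallest p per direction as values.

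Alternatives fixed beforehand were DESeq2 1.42.0, relative log expression size factors, no filter (36654 genes), no batch term, only the groups compared, the libraries of 1 batch, and the replicate number as a block. Alternatives chosen after seeing the data were leaving out aged isotype replicate 7, leaving out libraries with a TMM factor under 0.8, the B cell list level or the length trend as a covariate, and limma on list levels. The procedure was tested on 17671 uncorrelated genes simulated from the real means and library sizes. Of 100 genes changed 2-fold and 100 changed 4-fold it recovered 65 and 98 for anti-PD-L1 against isotype in young mice, 49 and 94 for the same in aged mice, and 54 and 99 for aged against young under anti-CTLA4. False calls numbered 6, 0 and 8 of 17471 unchanged genes. A planted list was found and 0 of 30 null lists called in each, with correlation untested. Per comparison 99 other splits of libraries, drawn with a fixed seed, were refitted.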

Results

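The transcriptome was measured by poly(A)-selected, strand-marked RNA sequencing in 52 tumours of 4T1, a mouse mammary carcinoma line that grows in the fat pad of Balb/C mice. Mice were young (8 to 10 weeks, with a protocol range reaching 12) or aged (more than 12 months). Each received 3 doses of 200 µg of 1 antibody on days 7, 10 and 13. Anti-PD-L1 and anti-CTLA4 bind proteins that inhibit T cells, and the third antibody was an isotype control. The young groups held 7 isotype, 10 anti-PD-L1 and 12 anti-CTLA4 libraries, and the aged groups held 7, 8 and 8. Total counts per library ran from 9549847 to 53778370 with a median of 20665734. The labels number the libraries of a group as biological replicates without naming the animal, so p-values measure the spread between these libraries.

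Sequencing was done in 3 batches that were not balanced over the groups. All 7 young isotype libraries came from batch 2, which held no aged library. Aged isotype came from batches 1 (3 libraries) and 3 (4 libraries). Aged anti-PD-L1 came from batch 1 alone. The comparisons of aged with young mice under isotype and under anti-PD-L1 therefore had no batch in common between their groups, and rested on the batch differences estimated from the other groups. Young anti-CTLA4 was spread over batches 1, 2 and 3 with 4, 3 and 5 libraries. Markers of B cells, which are abundant in lymph nodes, differed between libraries of every group, with list levels (mean log2 CPM) from -0.27 to 6.37 within young anti-PD-L1 and from -0.82 to 5.90 within aged anti-PD-L1.

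The first comparison asked which genes anti-PD-L1 changed relative to isotype in young mice. Parvb, which encodes the focal adhesion protein beta-parvin, fell from 92.2 ± 48.7 CPM (mean ± SD, n = 7) to 33.9 ± 7.27 CPM (n = 10), a log2 fold change of -1.42 ± 0.19 (SE), edgeR adjusted p = 7.28e-06. So did Map3k7cl (-2.10 ± 0.31, adjusted p = 0.000101) and Smarca2 (-1.13 ± 0.19, adjusted p = 0.000985). Rpl37rt (-2.60 ± 0.40) and Ube2n-ps1 (-3.67 ± 0.61) also fell. Both are processed copies of other genes, so their counts are uncertain. Slc30a1, a zinc exporter, rose from 5.82 ± 1.56 to 12.9 ± 5.58 CPM (1.08 ± 0.25, adjusted p = 0.0163). Fhl1 (1.27 ± 0.31), Pycr1, an enzyme of proline synthesis (0.87 ± 0.22), and Egfr (1.25 ± 0.31) rose as well. So did Camkmt (0.69 ± 0.16), the hyaluronan-binding protein Tnfaip6 (1.35 ± 0.34) and heme oxygenase Hmox1 (1.28 ± 0.33). These 6 had adjusted p = 0.0183 to 0.032.

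Altogether 40 genes rose and 245 fell among 17899 tested. The named genes lay beyond the isotype median in 9 to 10 of the 10 anti-PD-L1 libraries. The high Parvb mean of young isotype rested in part on replicates 6 and 5, at 190 and 126 CPM. Within batch 2 alone (7 isotype and 9 anti-PD-L1 libraries) 138 genes passed, 3 higher and 135 lower, of which 96 were among the 285, and of the higher genes named Hmox1 alone passed. With only the groups compared 2 genes were higher and 140 lower. Without the 4 libraries of lowest TMM factor, young isotype replicates 1 and 6, aged isotype replicate 3 and young anti-CTLA4 replicate 8, 18 genes passed, all of them lower and all among the 285. Of 99 other splits of these libraries 12 called as many, and the highest 5741.

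Of the 33 gene lists, 6 passed camera in this comparison, and none held when the correlation between genes was estimated from the residuals (adjusted p = 0.83 to 0.962 with an estimated correlation). Fibroblast markers were higher in 15 of 16 members (median 0.55, adjusted p = 1.35e-05), led by Col14a1, which rose (1.02 ± 0.26, adjusted p = 0.0347). Pi16, a marker of adventitial fibroblasts, was at 1.24 ± 0.36, adjusted p = 0.0581. TGF-beta and extracellular matrix genes were higher in 22 of 24 members (median 0.52, adjusted p = 1.35e-05), among them the collagen cross-linking enzyme Lox (1.14 ± 0.33, adjusted p = 0.0559) and the gelatinase Mmp2 (1.26 ± 0.43, adjusted p = 0.0934). Adipocyte markers such as the acyl-CoA synthetase Acsl1 (0.74 ± 0.26) and the lipid droplet protein Plin4 (1.33 ± 0.52) were higher in 14 of 14 (median 0.69, adjusted p = 0.0045). Natural killer cell markers were lower in 11 of 11 members (median -0.78, adjusted p = 0.000762). The chemokine Xcl1 was at -1.14 ± 0.35, adjusted p = 0.0713 and the receptor Klre1 at -1.17 ± 0.41, adjusted p = 0.099. Ribosomal protein genes were lower in 26 of 26 (median -0.74, adjusted p = 1.31e-10) and oxidative phosphorylation genes in 23 of 26 (median -0.37, adjusted p = 1.48e-05). Examples were Rps7 (-1.08 ± 0.32), Rps19 (-1.05 ± 0.31), the complex I subunit Ndufa2 (-0.92 ± 0.27) and the cytochrome oxidase subunit Cox7a2 (-1.06 ± 0.32). A length trend, the slope of a library's log2 CPM (as deviations from each gene's mean) on the log2 of effective gene length, differed as well, by 0.196 ± 0.088. The ribosomal list level differed by -0.62 ± 0.25 without and -0.10 ± 0.12 with the trend as a covariate, with which 1 gene passed as higher and 32 as lower. Adjusted over the list alone, 9 fibroblast, 5 matrix, 5 natural killer, 24 ribosomal, 10 oxidative phosphorylation and 0 adipocyte genes passed, against 1 fibroblast gene and 0 of the others over all genes. List levels lay beyond the isotype median in 10 of 10, 7 of 10, 9 of 10, 10 of 10, 10 of 10 and 6 of 10 anti-PD-L1 libraries for fibroblast, matrix, adipocyte, natural killer, ribosomal and oxidative phosphorylation genes. The endothelial list did not pass (adjusted p = 0.0591), though its member Mmrn2 fell (-2.23 ± 0.48, adjusted p = 0.00938).

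Of 7 immune genes followed under the antibodies, none passed in young mice under anti-PD-L1. Cd274, which encodes PD-L1, was at 0.35 ± 0.26 and Pdcd1, which encodes its receptor PD-1, at -0.37 ± 0.36. Ctla4 was at -0.24 ± 0.42, interferon gamma (Ifng) at -0.33 ± 0.41 and its target chemokine Cxcl9 at -0.34 ± 0.35. Cd8a, a marker of cytotoxic T cells, was at -0.36 ± 0.58 and Foxp3, the regulatory T cell factor, at 0.41 ± 0.47. The smallest adjusted p of the 7 was 0.396 (Cd274).

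Anti-CTLA4 was compared with isotype in young mice in the same way. Parvb fell to 33.1 ± 9.96 CPM (-1.32 ± 0.26, adjusted p = 0.0214), below the isotype median in 12 of 12 libraries. The ribosomal protein copy Rpl37rt (-2.56 ± 0.49, adjusted p = 0.0214) and the zinc finger gene Zfp808 (-1.16 ± 0.23, adjusted p = 0.0225) fell as well. Sirt1, a NAD-dependent deacetylase, fell in the fit with a batch term (-0.65 ± 0.14, adjusted p = 0.0472). Its unadjusted means were 16.2 ± 2.13 CPM under isotype and 14.7 ± 4.85 CPM under anti-CTLA4. The zinc finger gene Zfp644 fell likewise (-0.64 ± 0.14, adjusted p = 0.0497). In all, 1 gene rose and 12 fell. The gene that rose, the predicted model Gm16759 (5.37 ± 1.05, adjusted p = 0.0214), lies outside the rule for named genes and was named after its value was seen. The isotype libraries were all from batch 2, where 3 anti-CTLA4 libraries stood beside them. Within that batch 0 genes passed in edgeR (484 with unadjusted p under 0.05). DESeq2 called 51 over all libraries. With no batch term 1240 genes passed, 699 higher and 541 lower, of which 7 were among the 13, and with no filter or without the 4 libraries of low TMM factor 7 and 6 passed.

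Of the gene lists, 12 were higher and 4 lower under anti-CTLA4 in young mice, and none held, at adjusted p = 0.569 to 0.737 with an estimated correlation. Macrophage markers were higher in 15 of 20 members (median 0.41, adjusted p = 3.56e-06), with the lipid carrier Apoe at 0.94 ± 0.23 and Adgre1, the F4/80 antigen, at 0.59 ± 0.22. Genes of MHC class II presentation were higher in 11 of 13 (median 0.48, adjusted p = 0.000229), among them the protease Ctss (0.68 ± 0.24) and the invariant chain Cd74 (0.85 ± 0.36). Immune checkpoint genes (median 0.38, adjusted p = 5.03e-05) were led by Vsir (0.65 ± 0.22) and Cd200r1 (0.67 ± 0.25). Interferon-gamma-induced genes (median 0.45, adjusted p = 0.00132) were led by the adhesion molecule Icam1 (0.50 ± 0.26) and the Fc receptor Fcgr1 (0.46 ± 0.26). Adipocyte markers (median 1.04, adjusted p = 4.85e-08) were led by Acsl1 (0.92 ± 0.36) and the desaturase Scd1 (1.16 ± 0.60). The neutrophil (median 0.32, adjusted p = 0.00415), type I interferon (median 0.24, adjusted p = 0.00428), inflammatory cytokine (median 0.16, adjusted p = 0.00428) and fibroblast lists (median 0.19, adjusted p = 0.00541) were higher too. So were regulatory T cell markers (median 0.48, adjusted p = 0.0224), MHC class I genes (median 0.13, adjusted p = 0.0263) and nucleic acid sensing genes (median 0.12, adjusted p = 0.0348).

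Mitochondrially encoded genes were lower under anti-CTLA4 in 13 of 13 members (median -0.47, adjusted p = 0.000203), for example mt-Nd3 (-0.83 ± 0.30). Ribosomal protein genes were lower in 26 of 26 (median -0.47, adjusted p = 0.000229), with Rps7 at -0.80 ± 0.39, but had a median of -0.04 without the 4 libraries of low TMM factor. Proliferation genes were lower in 26 of 26 (median -0.20, adjusted p = 0.000514) and B cell markers in 16 of 16 (median -1.84, adjusted p = 0.00314). No list member passed over all genes, while Apoe alone passed adjusted over the list alone. Unadjusted levels went against the fitted sign for B cell markers, at 1.48 ± 2.23 under isotype and 2.53 ± 2.34 under anti-CTLA4. The B cell and mitochondrial lists had medians of 1.17 and 0.21 with no batch term. The list levels of macrophage, MHC class II, checkpoint, interferon-gamma and adipocyte genes lay above the isotype median in 11 of 12, 11 of 12, 12 of 12, 10 of 12 and 12 of 12 libraries. None of the 7 followed genes passed. Cd274 was at 0.54 ± 0.35, Ctla4 at 0.52 ± 0.54, Pdcd1 at 0.71 ± 0.48 and Ifng at 0.48 ± 0.54. Cxcl9 was at 0.70 ± 0.44, Cd8a at -0.04 ± 0.78 and Foxp3 at 0.66 ± 0.60.

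In aged mice, anti-PD-L1 was compared with isotype over 8 and 7 libraries. The smallest p among lower genes belonged to granulocyte transcripts, namely Camp, the cathelicidin antimicrobial peptide (-4.87 ± 0.97, adjusted p = 0.0878), Prg2, the eosinophil major basic protein (-4.25 ± 0.92), and Elane, neutrophil elastase (-4.25 ± 0.92). The isotype mean of Camp (33.7 ± 83.3 CPM, n = 7) rested on replicate 7, at 223 CPM, with the next highest at 4.54 CPM. Without that library Camp was at -1.44, Prg2 at -0.23 and Elane at -0.57. Among higher genes the smallest p belonged to Cnot4, a ubiquitin ligase of the CCR4-NOT complex (0.78 ± 0.16, adjusted p = 0.0878), Polr1a, the catalytic subunit of RNA polymerase I (1.05 ± 0.26), and the casein kinase subunit Csnk2a1 (0.63 ± 0.16). No gene passed: edgeR called 0 of 17899 genes, with 5379 at an unadjusted p under 0.05. DESeq2 called 2381 (962 higher and 1419 lower). Within batch 1, which held 3 isotype and all 8 anti-PD-L1 libraries, edgeR again called 0, with 2419 at an unadjusted p under 0.05. The fit with no batch term called 83.

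In aged mice 4 lists passed under anti-PD-L1, and none held, at adjusted p = 0.993 with an estimated correlation. Ribosomal protein genes were lower in 26 of 26 members (median -0.85, adjusted p = 2.53e-10), with Rps18 at -1.30 ± 0.41. Oxidative phosphorylation genes were lower in 23 of 26 (median -0.50, adjusted p = 3.5e-06), with Ndufa2 at -1.10 ± 0.34. Neutrophil and granulocytic markers were lower in 17 of 20 (median -0.99, adjusted p = 0.0168), among them myeloperoxidase Mpo (-3.55 ± 0.80) and the calcium-binding alarmin S100a8 (-2.75 ± 0.64). TGF-beta and matrix genes were higher in 22 of 24 (median 0.59, adjusted p = 0.00717). Tgfb1 was at 0.40 ± 0.13 and the basement membrane collagen Col4a1 at 1.01 ± 0.35. Without aged isotype replicate 7 the neutrophil list no longer passed (median -0.49), with Mpo at -0.40 and S100a8 at -1. The length trend was higher under anti-PD-L1 by 0.308 ± 0.102. With the trend as a covariate the ribosomal (0.07), oxidative phosphorylation (0.06) and matrix medians (-0.11) had the opposite sign. Adjusted over the list alone, 25 ribosomal, 16 lower and 1 higher oxidative phosphorylation, 8 neutrophil and 0 matrix genes passed, against 0 over all genes. Levels of the ribosomal, oxidative phosphorylation, neutrophil and matrix lists lay beyond the isotype median in 8 of 8, 8 of 8, 6 of 8 and 5 of 8 libraries. None of the 7 followed genes passed. Cd274 was at 0.26 ± 0.30, Ctla4 at -0.33 ± 0.49, Pdcd1 at 0.00 ± 0.45 and Ifng at -0.65 ± 0.50. Cxcl9 was at -0.26 ± 0.41, Cd8a at 0.31 ± 0.69 and Foxp3 at 0.71 ± 0.54.

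Anti-CTLA4 in aged mice was set against the same 7 aged isotype libraries. Runx3 (0.83 ± 0.19, adjusted p = 0.0956), Cnot4 (0.59 ± 0.16) and the syndecan Sdc3 (0.79 ± 0.21) had the smallest p among higher genes. The cysteine protease inhibitors Stfa2 (-3.14 ± 0.70) and Stfa3 (-3.05 ± 0.69), near-identical paralogs whose counts are uncertain, and Camp (-4.12 ± 0.95, adjusted p = 0.0956) had the smallest among lower genes. These were at -0.96, -1.17 and -1.20 without aged isotype replicate 7. No gene passed: edgeR called 0 of 17899 genes, with 5321 at an unadjusted p under 0.05. DESeq2 called 1916 (507 higher and 1409 lower). Batch 1 alone, with 3 isotype and 7 anti-CTLA4 libraries, gave 0 in edgeR and 610 at an unadjusted p under 0.05. Under anti-CTLA4 4 lists passed, and none held, at adjusted p = 0.978 with an estimated correlation. Ribosomal protein genes were lower in 26 of 26 members (median -0.88, adjusted p = 2.35e-10), with Rps19 at -1.17 ± 0.38. Oxidative phosphorylation genes were lower in 23 of 26 (median -0.51, adjusted p = 1.8e-06), with Ndufa2 at -1.11 ± 0.33. The length trend was higher by 0.286 ± 0.098. The ribosomal list level differed by -0.78 ± 0.29 without and -0.02 ± 0.14 with it as a covariate. Over the 52 libraries a separate trend, computed over 12337 genes that left out ribosomal, respiratory chain and mitochondrial genes, went with the ribosomal list level with Pearson's r = -0.92 and Spearman's rho = -0.89 (permutation p = 1e-05 for each, the smallest that the resamples can give, and the same adjusted over 2 relations). The r was -0.89 without the 2 libraries farthest from the median trend.

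**Figure D1:**
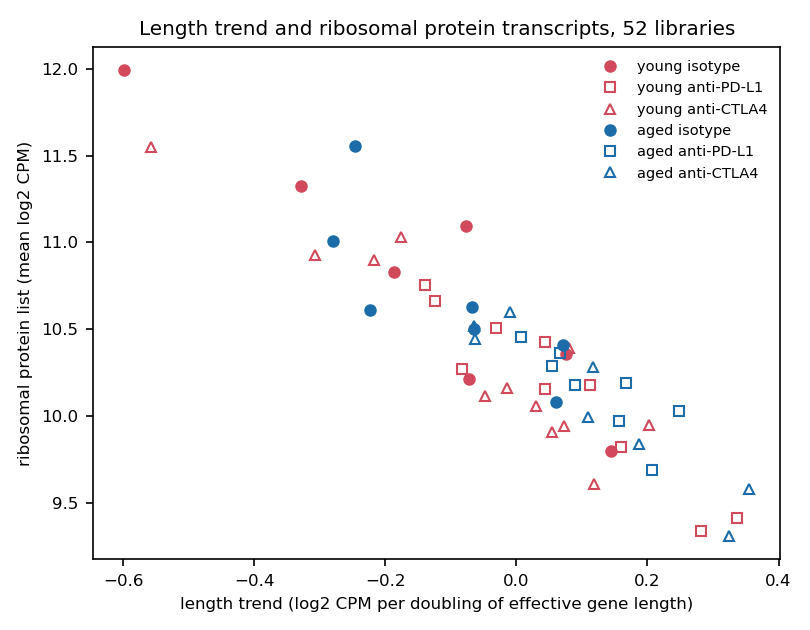
Ribosomal protein list level (mean log2 CPM) against the length trend (log2 CPM per doubling of effective gene length) in the 52 libraries, with young libraries in red, aged ones in blue and filled circles for isotype. Libraries with a higher trend had lower ribosomal levels within each batch (r = -0.91, -0.95 and -0.9).

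Adipocyte markers were higher in 13 of 14 members under anti-CTLA4 in aged mice (median 0.79, adjusted p = 0.00193), including Acsl1 (0.93 ± 0.29) and the triglyceride lipase Pnpla2 (0.76 ± 0.24). Markers of mammary secretory epithelium were higher in 12 of 14 (median 1.98, adjusted p = 0.00364), led by the milk fat protein Btn1a1 (2.45 ± 0.69) and beta-casein Csn2 (4.16 ± 1.37), both products of normal gland. Adjusted over the list alone, 26 ribosomal, 18 oxidative phosphorylation, 4 adipocyte and 7 mammary genes passed, against 0 over all genes. List levels lay beyond the isotype median in 8 of 8, 8 of 8, 6 of 8 and 7 of 8 libraries. None of the 7 followed genes passed. Foxp3 was at 1.21 ± 0.52, adjusted p = 0.122, Cd274 at 0.25 ± 0.29, Ctla4 at 0.46 ± 0.47, Pdcd1 at -0.31 ± 0.42 and Ifng at -0.44 ± 0.48. Cxcl9 was at -0.07 ± 0.39 and Cd8a at -0.14 ± 0.66.

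The next comparisons asked how tumours of aged mice differed from those of young mice under the same antibody. Under isotype, the serine/threonine kinase Pim1 fell in aged mice (-2.18 ± 0.30, adjusted p = 1.74e-05). So did Cyth1, an exchange factor for ARF GTPases, from 307 ± 226 to 28.6 ± 11 CPM (-3.60 ± 0.51, adjusted p = 1.74e-05). Parvb (-2.12 ± 0.31), the ubiquitin ligase Mid1 (-2.43 ± 0.38) and Mup10, a major urinary protein normally made by liver (-8.81 ± 1.44), fell as well, with adjusted p = 2.7e-05 to 0.00027. Nr1d2, a repressor of the circadian clock (1.30 ± 0.22, adjusted p = 0.000336), the stress kinase Mapk8 (1.19 ± 0.20, adjusted p = 0.000338) and the ubiquitin-conjugating enzyme Ube2q2 (1.20 ± 0.20, adjusted p = 0.000506) rose. In all 781 genes rose and 724 fell. The 8 named genes lay beyond the young isotype median in 7 of the 7 aged libraries. The count was 3261 with no batch term. Of 99 other splits of these libraries 4 called as many, and the highest 4004.

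Under isotype 14 lists passed for age, and none held, at adjusted p = 0.61 to 0.706 with an estimated correlation. Interferon-gamma-induced genes were lower in aged mice in 25 of 26 members (median -0.85, adjusted p = 2.19e-07), with the signalling inhibitor Socs1 (-1.56 ± 0.38, adjusted p = 0.00794) and Cd274 (-1.38 ± 0.43, adjusted p = 0.0385) among the 3 that fell. Cytotoxic lymphocyte genes (median -1.63, adjusted p = 1.01e-05) included the granzymes Gzma (-2.62 ± 0.66, adjusted p = 0.0101) and Gzmb (-2.19 ± 0.61, adjusted p = 0.0186), which were the 2 members that fell. MHC class I genes (median -0.59, adjusted p = 2.97e-05, 5 fell), among them the peptide transporter Tap2 (-1.14 ± 0.33, adjusted p = 0.0246), were lower too. So were inflammatory cytokines (median -0.82, adjusted p = 0.000464, 4 fell), among them the chemokine Ccl4 (-2.29 ± 0.59, adjusted p = 0.0119). Lower lists also included T cell markers (median -1.86, adjusted p = 1.45e-05), regulatory T cell markers (median -1.19, adjusted p = 0.00047), type I interferon-stimulated genes (median -0.56, adjusted p = 0.000761), and B cell markers (median -2.72, adjusted p = 0.0168). Natural killer markers (median -1.25, adjusted p = 0.0291), immunoglobulin genes (median -0.93, adjusted p = 0.0363), lymph node stroma (median -1.49, adjusted p = 0.0418), immediate early genes (median -0.46, adjusted p = 0.0425) and checkpoint genes (median -0.73, adjusted p = 0.0457) were lower as well. Carcinoma epithelial markers were higher in 14 of 14 members (median 0.81, adjusted p = 2.7e-06). The tight junction protein Cldn4 (1.94 ± 0.39, adjusted p = 0.00224) and keratin Krt7 (1.57 ± 0.33, adjusted p = 0.00305) were among the 3 that rose.

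With no batch term 6 lists passed, 2 higher and 4 lower, with B cell and immunoglobulin medians of 0.70 and 0.37. Unadjusted levels (aged, young) were nearer than fitted for T cell (2.999, 3.345) and cytotoxic genes (2.46, 2.98), not MHC class I (7.79, 8.39). Without aged isotype replicate 7 the immediate early list did not pass (median -0.40). A test of each list's mean level per library called epithelial markers higher (0.92 ± 0.25, adjusted p = 0.0182). Cytotoxic (-1.57 ± 0.54), MHC class I, regulatory T cell and immediate early genes were lower (adjusted p = 0.0437 each). Interferon-gamma genes did not pass (adjusted p = 0.0625). Adjusted over the list alone, 8 interferon-gamma, 8 cytotoxic, 7 MHC class I and 11 inflammatory genes passed as lower and 8 epithelial genes as higher. Levels of these lists lay beyond the young isotype median in 7 of 7 aged libraries (cytotoxic 5 of 7).

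Under anti-PD-L1, Mup10 (-10.56 ± 1.56, adjusted p = 7.73e-05) and Cyth1 (-2.98 ± 0.48, adjusted p = 0.000388) had the smallest p among genes that fell in aged mice. Next came Mup9 (-5.82 ± 0.98), a close paralog of Mup10 whose counts are uncertain, and the secreted phospholipase Pla2g5 (-3.61 ± 0.61, adjusted p = 0.00079). Xiap, an inhibitor of caspases (0.99 ± 0.17, adjusted p = 0.00079), the centrosomal protein Odf2l (1.12 ± 0.20, adjusted p = 0.00135), Nr1d2 (1.13 ± 0.21, adjusted p = 0.00272) and the mitochondrial transcription factor Tfb2m (0.88 ± 0.17, adjusted p = 0.00375) rose. So did Macc1, a regulator of the hepatocyte growth factor receptor, from 11 ± 4.67 to 38.9 ± 7.01 CPM (2.19 ± 0.44, adjusted p = 0.00406). In all 551 genes rose and 352 fell. The 9 named lay beyond the young median in all 8 aged libraries. With no filter 426 genes passed, with the replicate block 35. With no batch term 2192 did, 42.1% higher (61% with it).

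Under anti-PD-L1 22 lists passed for age, and none held, at adjusted p = 0.273 to 0.539 with an estimated correlation. Inflammatory cytokine genes were lower in 21 of 21 members in aged mice (median -1.17, adjusted p = 3.18e-10), and 9 fell, led by oncostatin M, Osm (-1.97 ± 0.36, adjusted p = 0.0019), and Ccl4 (-2.71 ± 0.58, adjusted p = 0.0072). Neutrophil markers (median -1.95, adjusted p = 1.67e-07) included 8 that fell, among them S100a9, from 229 ± 123 to 80.7 ± 42.7 CPM (adjusted p = 0.0143), and the chemokine Cxcl2 (-4.74 ± 1.18, adjusted p = 0.016). Of 9 erythroid and blood genes 5 fell (median -1.98, adjusted p = 8.05e-06), including platelet factor Pf4 (-3.49 ± 0.74, adjusted p = 0.0072) and the haemoglobin gene Hba-a1 (-2.17 ± 0.56, adjusted p = 0.019), whose near-identical copy makes its counts uncertain. The interferon-gamma (median -0.86, adjusted p = 9.68e-09), MHC class I (median -0.66, adjusted p = 1.35e-06), regulatory T cell (median -1.16, adjusted p = 2.87e-06), cytotoxic (median -1.23, adjusted p = 4.81e-06) and senescence lists (median -0.58, adjusted p = 0.00234) were lower. Members that fell included Socs1 (-1.76 ± 0.37, adjusted p = 0.0062), Il10 (-3.42 ± 0.75, adjusted p = 0.009) and Ccl8 (-3.08 ± 0.66, adjusted p = 0.0072). T cell (median -1.62, adjusted p = 2.81e-07), B cell (median -2.71, adjusted p = 0.000345), immunoglobulin (median -2.19, adjusted p = 4.64e-05) and lymph node lists (median -1.67, adjusted p = 0.0093) were lower with 0 members past the threshold.

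Under anti-PD-L1 the lists lower in aged mice also included type I interferon (median -0.39, adjusted p = 0.0024), checkpoint (median -0.51, adjusted p = 0.00366), MHC class II (median -0.50, adjusted p = 0.00592), and adipocyte genes (median -0.81, adjusted p = 0.00602). Endothelial (median -0.56, adjusted p = 0.00863), immediate early (median -0.35, adjusted p = 0.0296), fibroblast (median -0.43, adjusted p = 0.0336) and macrophage genes (median -0.43, adjusted p = 0.0463) were lower too. Epithelial (median 0.59, adjusted p = 4.33e-05) and proliferation lists (median 0.24, adjusted p = 0.0043) were higher. Members that rose included Krt7 (1.41 ± 0.32, adjusted p = 0.0104) and Bub1 (0.83 ± 0.21, adjusted p = 0.0181). The test of list levels called 1 higher and 10 lower. Inflammatory genes had a level difference of -1.48 ± 0.34 (adjusted p = 0.00277) and lay below the young median in 8 of 8 libraries. Neutrophil markers had one of -1.90 ± 0.52 (adjusted p = 0.00752, 8 of 8 libraries). As lower, 14 inflammatory, 14 neutrophil, 8 erythroid and 13 MHC class I genes passed adjusted over the list alone. With no batch term 12 lists passed (B cell median 0.22). Without aged isotype replicate 7 the macrophage list did not pass (-0.45).

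Under anti-CTLA4, where batch 1 held 4 young and 7 aged libraries, Mid1 (-2.19 ± 0.24, adjusted p = 2.57e-08) and Cyth1 (-3.12 ± 0.35, adjusted p = 2.57e-08) fell in aged mice with the smallest p. Next came Ninj1, a membrane protein of lytic cell death (-1.66 ± 0.19, adjusted p = 1.04e-07), and Sh3bgrl3 (-1.03 ± 0.12, adjusted p = 1.28e-07). The zinc finger gene Zfp81 (0.97 ± 0.12, adjusted p = 3.38e-07), Xiap (0.93 ± 0.12, adjusted p = 3.38e-07), Tbc1d8b (1.56 ± 0.20, adjusted p = 3.38e-07) and the membrane protease Tmprss11e (1.93 ± 0.25, adjusted p = 8.03e-07) rose. Macc1 reached 35.9 ± 4.86 CPM against 8.93 ± 4.97 (2.21 ± 0.32, adjusted p = 2.84e-06). In all 2644 genes rose and 2841 fell. The 9 named genes lay beyond the young median in 8 of the 8 aged libraries. Within batch 1, 3596 genes passed, of which 3316 were among the 5485. The length trend averaged -0.063 in the young and 0.119 in the aged libraries, and 4 of 99 other splits differed by at least this (0.183). With the trend as a covariate 6616 genes passed, of which 3963 were among the 5485.

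Under anti-CTLA4 18 lists passed for age, and none held, at adjusted p = 0.262 to 0.757 with an estimated correlation. Genes of T and natural killer cells were lower in aged mice. Cytotoxic genes fell in 16 of 17 members (median -1.91, adjusted p = 3.73e-09), with Gzmb at -2.90 ± 0.39, adjusted p = 1.38e-06 and Gzma at -2.80 ± 0.47, adjusted p = 2.42e-05. T cell markers fell in 15 of 20 (median -1.82, adjusted p = 3.59e-06), among them the receptor chain Cd3d (-3.05 ± 0.68, adjusted p = 0.000648). Natural killer markers fell in 10 of 11 (median -1.40, adjusted p = 1.76e-05), among them Xcl1 (-2.16 ± 0.37, adjusted p = 3.26e-05). Interferon-gamma-induced genes fell in 22 of 26 (median -1.12, adjusted p = 3.73e-09), including Socs1, from 60.5 ± 19.7 to 17 ± 4.15 CPM (adjusted p = 4.26e-07), and Cd274 (-1.66 ± 0.28, adjusted p = 2.29e-05). MHC class I genes fell in 19 of 23 (median -0.87, adjusted p = 6.35e-08) and MHC class II genes in 10 of 13 (median -1.30, adjusted p = 7.36e-06). Checkpoint genes fell in 12 (median -0.89, adjusted p = 1.76e-05), with the PD-1 ligand Pdcd1lg2 at -2.99 ± 0.42, adjusted p = 1.95e-06. Regulatory T cell markers fell in 7 (median -1.21, adjusted p = 5.59e-05).

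Myeloid and inflammatory genes were lower as well under anti-CTLA4. Inflammatory cytokines fell in 17 of 21 members (median -1.06, adjusted p = 2.53e-09), with Ccl4 at -2.75 ± 0.37, adjusted p = 1.35e-06 and tumour necrosis factor, Tnf, at -1.90 ± 0.26, adjusted p = 1.69e-06. Neutrophil markers fell in 17 of 20 (median -2.16, adjusted p = 4.31e-07), with S100a9 at -3.33 ± 0.63, adjusted p = 0.000114. Macrophage markers fell in 8 (median -0.45, adjusted p = 0.00114), led by the lysosomal protein Cd68 (-1.26 ± 0.19, adjusted p = 4.04e-06). Type I interferon genes fell in 17 (median -0.62, adjusted p = 0.00011), erythroid genes in 7 (median -1.67, adjusted p = 0.00042), senescence-associated genes in 7 (median -0.32, adjusted p = 0.0335) and ribosomal protein genes in 2 (median -0.55, adjusted p = 0.00582). Epithelial markers rose in 7 of 14 (median 0.65, adjusted p = 0.00011), with Krt7 at 1.38 ± 0.22, adjusted p = 1.27e-05 and the adhesion molecule Epcam at 1.07 ± 0.19, adjusted p = 5.49e-05. Proliferation genes rose in 6 (median 0.30, adjusted p = 0.000557) and mitochondrially encoded genes in 1 (median 0.40, adjusted p = 0.0335). Skeletal muscle, skin keratinocyte and hypoxia lists did not pass (adjusted p = 0.619, 0.985 and 0.34). Of their members, the muscle troponin Tnnt3 (2.48 ± 0.55, adjusted p = 0.000614), the skin protein Sbsn (-1.70 ± 0.36, adjusted p = 0.000418) and Vegfa (-1.12 ± 0.30, adjusted p = 0.00403) passed.

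The test of list levels called 2 higher and 15 lower. Level differences were -1.91 ± 0.36 for cytotoxic genes (adjusted p = 4.76e-05, below the young median in 8 of 8 libraries), -1.12 ± 0.27 for interferon-gamma genes (adjusted p = 0.000514, 8 of 8) and -1.35 ± 0.23 for inflammatory genes (adjusted p = 1.91e-05, 8 of 8). Adjusted over the list alone, 16 cytotoxic, 18 T cell, 11 natural killer, 23 interferon-gamma and 17 inflammatory genes passed as lower and 8 epithelial genes as higher. With the length trend as a covariate the ribosomal median was 0.14.

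**Figure D2:**
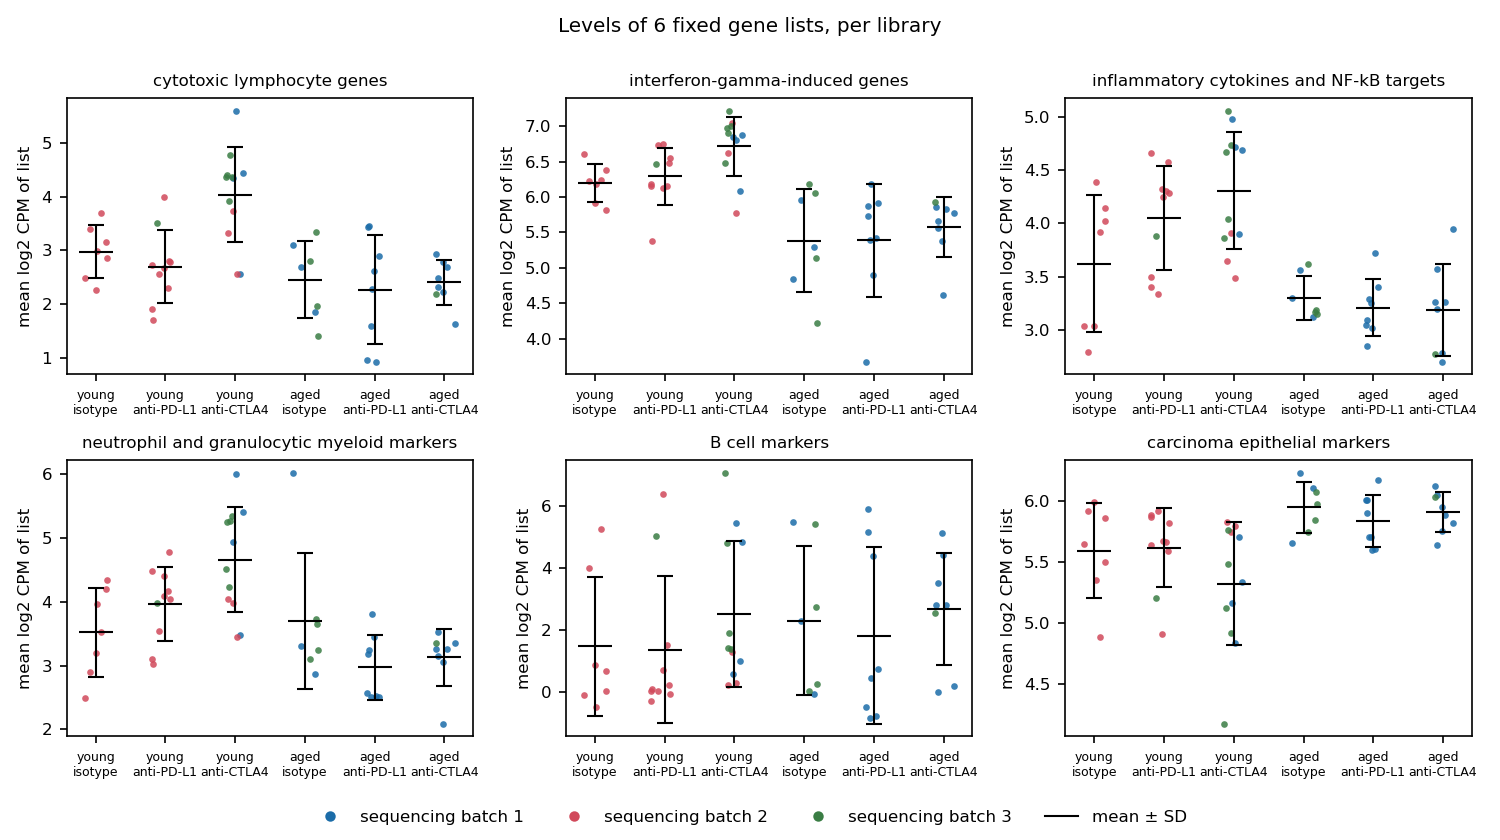
Mean log2 CPM of 6 gene lists in each of the 52 libraries by group, coloured by sequencing batch, with bars for the mean ± SD. Cytotoxic genes lay at 4.03 ± 0.88 in young and 2.41 ± 0.41 in aged anti-CTLA4 tumours.

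The 3 age comparisons shared no library but shared the fitted batch term. In all 3, 392 genes rose and 176 fell, against 3.55 and 2.26 for independent lists of these sizes, and 0 genes passed in opposite directions. The counts were 194 and 69 with no filter, 1280 and 682 with the length covariate and 13 and 14 with the replicate block. Of the genes on the fixed lists, Ccl2, Ccl3, Ccl4, Cd274, Cd68, Cdkn1a, Gzma, Gzmb, Il10, Mmrn2, Osm, Pdcd1lg2, Socs1, Tigit and Zfp36 fell in all 3, and Bub1, Cgas, Epcam, Klf6, Krt7 and Tnnt3 rose in all 3. Macc1 (ENSMUSG00000041886, chromosome 12, 119314270 to 119469987, GRCm38) ranged from 2.41 to 16.3 CPM over the 29 young libraries and from 29.8 to 53.6 over the 23 aged libraries. Cyth1 (ENSMUSG00000017132) ranged from 80.6 to 854 CPM in young and from 17.9 to 50.6 in aged libraries. Mid1 (ENSMUSG00000035299) ranged from 12.8 to 49.8 and from 4.46 to 12.6 CPM. Mup10 (ENSMUSG00000078680) ranged from 8.47 to 307 CPM in young libraries and reached at most 6.91 CPM in aged ones, where its group means were 0.319, 0.113 and 0.863 CPM. Its fitted fold therefore depends on the prior count.

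**Figure D3:**
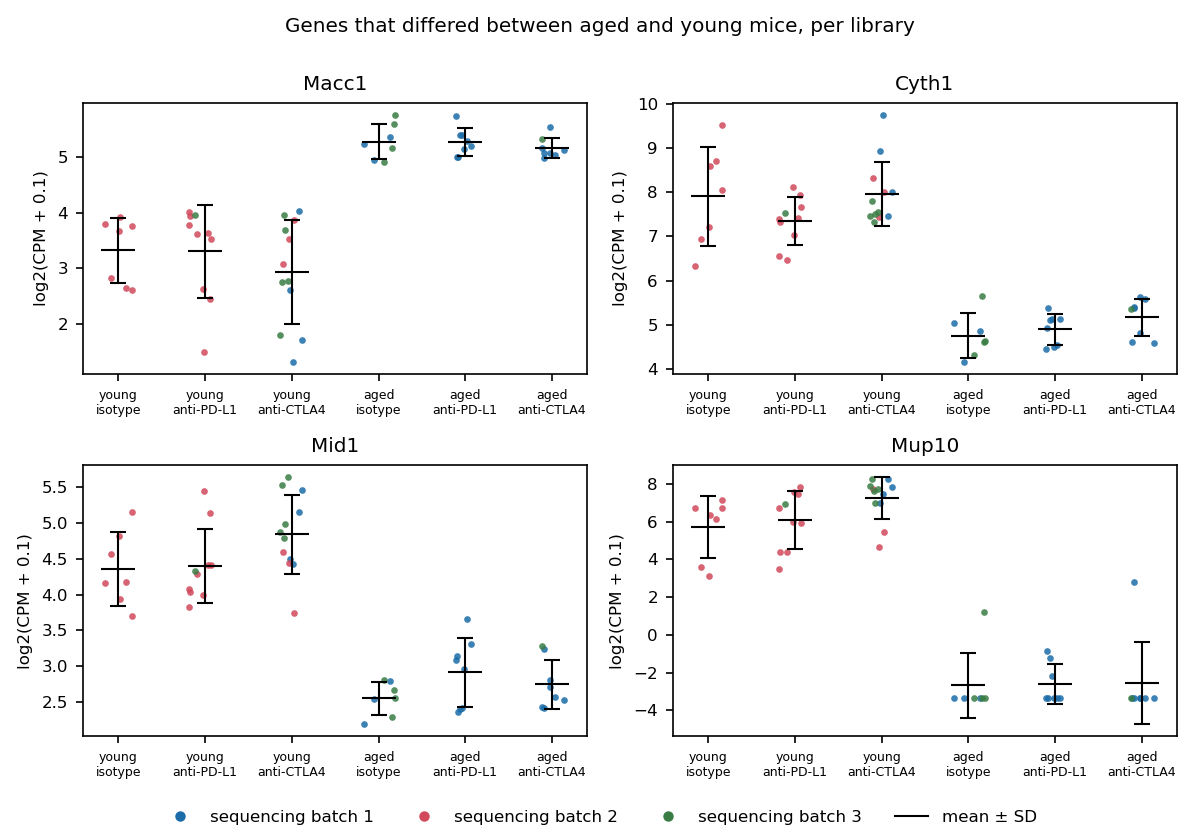
Log2(CPM + 0.1) of Macc1, Cyth1, Mid1 and Mup10 in each library by group, coloured by sequencing batch, with bars for the mean ± SD. Macc1 ranged from 29.8 to 53.6 CPM in aged and 2.41 to 16.3 in young libraries.

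Whether the response to anti-PD-L1 differed between aged and young mice was tested as a difference of the 2 effects. Parvb (1.47 ± 0.29, adjusted p = 0.0755) and the transcription coactivator Crtc3 (1.39 ± 0.28, adjusted p = 0.0755) were among the 3 genes of smallest p with a higher effect in aged mice. The peroxisomal racemase Amacr (-0.67 ± 0.17, adjusted p = 0.315), Prg2 (-4.44 ± 1.22) and Camp (-4.53 ± 1.28) had the smallest p among those with a lower effect, the last 2 at -0.34 and -1.04 without aged isotype replicate 7. Among the 7 followed genes, those with the smallest p were Cd8a (0.67 ± 0.91), Pdcd1 (0.37 ± 0.58) and Ifng (-0.32 ± 0.65), each with adjusted p = 1. No gene passed: edgeR called 0 of 17899 genes, with 655 at an unadjusted p under 0.05. DESeq2 called 31 (26 higher and 5 lower).

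Of the lists, 10 passed for this difference, and none held, at adjusted p = 0.37 to 0.967 with an estimated correlation, or in the test of list levels (smallest adjusted p = 0.694). The effect of anti-PD-L1 was lower in aged than in young mice for neutrophil markers (median -1.60, adjusted p = 1.71e-09, 19 of 20 members lower), with the granulocyte antigen Ly6g at -3.67 ± 1.00. It was also lower for fibroblast markers (median -0.57, adjusted p = 7.2e-07, 14 of 16), with Mfap5 at -0.90 ± 0.26. It was lower for erythroid (median -0.97, adjusted p = 3.09e-05), adipocyte (median -0.80, adjusted p = 8.13e-05), inflammatory (median -0.40, adjusted p = 0.000249), epithelial (median -0.13, adjusted p = 0.0413), senescence (median -0.29, adjusted p = 0.0413), immunoglobulin (median -1.05, adjusted p = 0.0421) and ribosomal genes (median -0.15, adjusted p = 0.0468). It was higher for proliferation genes (median 0.14, adjusted p = 0.0466). Adjusted over the list alone, 8 neutrophil genes and 1 fibroblast gene passed, against 0 over all genes. Without aged isotype replicate 7 the neutrophil median was -0.48, the ribosomal one -0.25, Ly6g was at -1.43 and the immunoglobulin list did not pass (-0.40). Ribosomal medians were 0.43 within batches (isotype ages shared none), 0.15 with no batch term and 0.16 with the length covariate.

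The same difference for anti-CTLA4 gave 0 genes in edgeR, with 1257 at an unadjusted p under 0.05, and 18 in DESeq2. Sirt1 (0.84 ± 0.18, adjusted p = 0.226) and the cadherin Celsr1 (1.88 ± 0.42, adjusted p = 0.244) were among the 3 genes of smallest p with a higher effect in aged mice. The ATP receptor P2rx4 (-0.86 ± 0.22, adjusted p = 0.29), the chemokine Ccl17 (-2.59 ± 0.66) and Amacr (-0.73 ± 0.19) had the smallest p among those with a lower one. Pdcd1 was at -1.02 ± 0.63, Cxcl9 at -0.77 ± 0.58 and Ifng at -0.91 ± 0.71, none of which passed. Of the lists, 13 passed, and none held, at adjusted p = 0.847 with an estimated correlation, or in the test of list levels. Mitochondrially encoded genes had a higher effect in aged mice in 13 of 13 members (median 0.77, adjusted p = 1.47e-05), with mt-Atp8 at 1.18 ± 0.52. So did B cell (median 1.39, adjusted p = 0.00737), proliferation (median 0.26, adjusted p = 0.0233) and mammary lists (median 1.74, adjusted p = 0.0328). Oxidative phosphorylation genes had a lower one in 24 of 26 (median -0.45, adjusted p = 1.66e-05). So did neutrophil (median -1.06, adjusted p = 5.1e-05), ribosomal (median -0.39, adjusted p = 0.000207), MHC class II (median -0.63, adjusted p = 0.00543), inflammatory (median -0.24, adjusted p = 0.00903), macrophage (median -0.29, adjusted p = 0.0219), checkpoint (median -0.33, adjusted p = 0.0346), keratinocyte (median -0.28, adjusted p = 0.0426) and erythroid genes (median -0.56, adjusted p = 0.0483). Of neutrophil genes 5 passed adjusted over the list alone. Without aged isotype replicate 7 the neutrophil median was -0.30 and the B cell one 2.61, and the checkpoint (-0.30) and erythroid lists (-0.39) did not pass. The B cell median was -1.71 with no batch term. With the length trend as a covariate the ribosomal median was 0.20.

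The antibodies were last compared with each other within an age. In young mice, Zmynd15 (0.94 ± 0.18, adjusted p = 0.0672), the small GTPase Rab25 (1.60 ± 0.37, adjusted p = 0.311) and Tifab (0.61 ± 0.14, adjusted p = 0.311) had the smallest p among genes higher under anti-CTLA4. The iron exporter Slc40a1 (-1.64 ± 0.42, adjusted p = 0.347) and the immunoglobulin segments Igkv3-4 (-7.66 ± 1.99) and Igkv3-11 (-6.27 ± 1.63), whose reads can be shared within their family, had it among genes lower. Cxcl9 (1.04 ± 0.38), Pdcd1 (1.08 ± 0.43) and Ifng (0.81 ± 0.48) did not pass. No gene passed: edgeR called 0 of 17899 genes, with 1242 at an unadjusted p under 0.05. DESeq2 called 13 (9 higher and 4 lower). Of the lists, 17 passed, and none held, at adjusted p = 0.487 to 0.609 with an estimated correlation, or in the test of list levels. Natural killer markers were higher under anti-CTLA4 in 11 of 11 members (median 0.83, adjusted p = 3.99e-08), with the receptor Klrb1b at 1.33 ± 0.33. MHC class II genes were higher in 11 of 13 (median 0.73, adjusted p = 1.08e-06), with H2-DMa at 0.73 ± 0.21. Oxidative phosphorylation (median 0.30, adjusted p = 8.94e-06), cytotoxic (median 0.58, adjusted p = 4.11e-05), checkpoint (median 0.24, adjusted p = 0.000158), and ribosomal lists (median 0.27, adjusted p = 0.000423) were higher. Macrophage (median 0.26, adjusted p = 0.000459), MHC class I (median 0.19, adjusted p = 0.0014), regulatory T cell (median 0.45, adjusted p = 0.00299), type I interferon (median 0.24, adjusted p = 0.00479), interferon-gamma (median 0.23, adjusted p = 0.00789) and adipocyte lists (median 0.22, adjusted p = 0.012) were higher too. Mitochondrially encoded (median -0.58, adjusted p = 7.16e-07), matrix (median -0.59, adjusted p = 0.000233), immunoglobulin (median -2.08, adjusted p = 0.00303), B cell (median -2.13, adjusted p = 0.00308) and fibroblast lists (median -0.38, adjusted p = 0.0198) were lower.

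As higher, 5 natural killer, 8 MHC class II, 6 macrophage and 1 interferon-gamma genes passed adjusted over the list alone, against 0 over all genes. List levels of natural killer and MHC class II genes lay above the anti-PD-L1 median in 12 of 12 and 12 of 12 anti-CTLA4 libraries. In batch 2 alone (9 and 3 libraries) edgeR called 0 genes, with 2564 at an unadjusted p under 0.05. With no batch term the B cell and immunoglobulin tests turned (medians 0.60 and -0.73), and with the length trend as a covariate the ribosomal and matrix tests (-0.12 and -0.08).

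In aged mice, adipocyte markers were higher under anti-CTLA4 than under anti-PD-L1 in 14 of 14 members (median 0.93, adjusted p = 3.81e-30). Regulatory T cell markers were higher in 12 of 12 (median 0.46, adjusted p = 3.05e-15), with Tnfrsf4 at 0.63 ± 0.32 and Ctla4 at 0.78 ± 0.42. Both passed with the correlation estimated (adjusted p = 0.0166 with an estimated correlation) but not in the test of list levels (adjusted p = 0.615 and 0.626). Their levels lay above the anti-PD-L1 median in 6 of 8 and 7 of 8 libraries. No single gene passed: edgeR called 0 of 17899 genes, with 243 at an unadjusted p under 0.05. DESeq2 called 18 (6 higher and 12 lower). The smallest p belonged to Igkv4-79 (4.52 ± 1.28, adjusted p = 0.774), the lectin Cd209e (1.33 ± 0.45) and Adhfe1 (0.57 ± 0.20) among higher genes. Among lower ones it belonged to Grip2 (-3.89 ± 0.89, adjusted p = 0.31), C2cd4c (-3.51 ± 0.86) and Igkv12-38 (-6.21 ± 1.59). Foxp3 was at 0.50 ± 0.46 and Pdcd1 at -0.30 ± 0.37.

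Of the other lists, 13 were higher under anti-CTLA4 in aged mice by camera, and none held, at adjusted p = 0.639 to 0.687 with an estimated correlation, or in the test of list levels. They were dendritic cell (median 0.07, adjusted p = 0.000593), interferon-gamma (median 0.02, adjusted p = 0.00183), fibroblast (median 0.05, adjusted p = 0.00821), MHC class I (median 0.08, adjusted p = 0.00828), type I interferon (median 0.01, adjusted p = 0.0217) and 8 more. Camera gave the T cell (median -0.13, adjusted p = 3.16e-08), B cell (median -0.46, adjusted p = 7.72e-07), cytotoxic (median -0.24, adjusted p = 0.0211), immunoglobulin (median -0.80, adjusted p = 0.00989) and lymph node lists (median -0.10, adjusted p = 0.0126) as higher although the median and mean of their edgeR fold changes were negative. The natural killer (median 0.01, adjusted p = 0.0384), MHC class II (median 0.04, adjusted p = 0.0183) and mammary lists (median 0.13, adjusted p = 0.00197) had a positive median and a negative mean.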

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

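In this part the quantities searched for distant libraries were chosen after results had been seen, while the list tests of the differences of effects were fixed before the data were examined. Of 220 groups of values, 19 had a library whose gap to the next exceeded Dixon's limit for the group's range, where chance gives about 1 in 20 groups. Among aged anti-CTLA4 libraries, replicate 1 had the lowest levels (mean log2 CPM) of interferon-gamma-induced genes, 4.61 (next 5.38), MHC class I genes, 7.29 (next 7.68), and neutrophil markers, 2.08 (next 3.05), and the highest of proliferation genes, 6.35 (next 6.11). Replicate 6 of the same group had the lowest erythroid level, 1.51 (next 2.35), and the highest Cd8a, 31.4 (next 15.7) CPM. Among aged isotype libraries, replicate 7 had a neutrophil level of 6.02 (next 3.72), replicate 4 a fibroblast level of 6.05 (next 5.5) and a Foxp3 level of 5.35 (next 2.45) CPM, replicate 1 a skeletal muscle level of 3.06 (next 1.84) and replicate 6 a senescence level of 5.19 (next 4.92), each the highest of its group. Aged anti-PD-L1 replicate 8 had the highest TMM factor, 1.16 (next 1.08), and replicate 2 the lowest keratinocyte level, -0.373 (next 0.617).

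Among young anti-PD-L1 libraries, replicate 3 had the highest Pdcd1, 17.5 (next 9.55) CPM, and Cd8a, 57.4 (next 27.1) CPM, replicate 2 the lowest interferon-gamma level, 5.37 (next 6.13), and replicate 6 the lowest proliferation level, 5.22 (next 5.96). Among young isotype libraries, replicate 5 had the highest fibroblast level, 5.87 (next 5.1), and replicate 2 the highest Ctla4, 9.72 (next 5.54) CPM.

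The effects of an antibody differed between aged and young mice for 10 lists under anti-PD-L1 and 13 under anti-CTLA4 by camera with the preset correlation, and for 0 with the correlation estimated from the residuals. For anti-PD-L1 the lists with a lower effect in aged mice, with adjusted p, were neutrophil (1.71e-09), fibroblast (7.2e-07), erythroid (3.09e-05), adipocyte (8.13e-05), inflammatory (0.000249), epithelial (0.0413), senescence (0.0413), immunoglobulin (0.0421) and ribosomal (0.0468), and the list with a higher one was proliferation (0.0466). For anti-CTLA4 those with a lower effect were oxidative phosphorylation (1.66e-05), neutrophil (5.1e-05), ribosomal (0.000207), MHC class II (0.00543), inflammatory (0.00903), macrophage (0.0219), checkpoint (0.0346), keratinocyte (0.0426) and erythroid (0.0483), and those with a higher one mitochondrial (1.47e-05), B cell (0.00737), proliferation (0.0233) and mammary (0.0328).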

How the results depend on the processing

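The DESeq2, filter, batch term, group, within-batch and block alternatives were fixed before the data were examined, and the tests without libraries, with a covariate and of list levels were chosen after the results were seen. Here an antibody in mice of an age is named for its comparison with isotype, and age for aged against young. Relative log expression size factors moved no count by over 1.5 times and turned no named gene. The cause of the moves was not tested, except that the fits without libraries, of the groups compared and of 1 batch held fewer libraries and the unfiltered fit adjusted over 36654 genes. A count of 0 is from edgeR, and DESeq2's counts follow.

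With DESeq2 in place of edgeR, 863 genes passed for anti-PD-L1 in young mice, 51 for anti-CTLA4 in young mice, 2381 for anti-PD-L1 in aged mice, 1916 for anti-CTLA4 in aged mice, 1532 for age under anti-PD-L1, 31 for the difference of anti-PD-L1 effects, 18 for the difference of anti-CTLA4 effects, 13 for the antibodies in young mice and 18 for the antibodies in aged mice. With no low-count filter, 153 genes passed for anti-PD-L1 in young mice, 7 for anti-CTLA4 in young mice, 4 for anti-PD-L1 in aged mice, 3 for anti-CTLA4 in aged mice and 426 for age under anti-PD-L1. Gene estimates that turned were 0.01 (Pdcd1) for anti-PD-L1 in aged mice and 0.01 (Cd8a) for anti-CTLA4 in young mice. With no batch term, 1240 genes passed for anti-CTLA4 in young mice, 83 for anti-PD-L1 in aged mice, 6 for anti-CTLA4 in aged mice, 3261 for age under isotype, 2192 for age under anti-PD-L1, 18 for the difference of anti-PD-L1 effects, 10 for the difference of anti-CTLA4 effects and 306 for the antibodies in young mice. There 6 lists passed for age under isotype and 12 for age under anti-PD-L1. List tests that turned had medians of 1.17 (B cell) and 0.21 (mitochondrial) for anti-CTLA4 in young mice, 0.70 (B cell) and 0.37 (immunoglobulin) for age under isotype, 0.22 (B cell) for age under anti-PD-L1, 0.15 (ribosomal) for the difference of anti-PD-L1 effects, -1.71 (B cell) for the difference of anti-CTLA4 effects and 0.60 (B cell) and -0.73 (immunoglobulin) for the antibodies in young mice. Genes turned with estimates of 0.03 (Cxcl9) for anti-CTLA4 in aged mice, 0.20 (Pdcd1) for anti-PD-L1 in aged mice, -0.41 (mt-Atp8) for the difference of anti-CTLA4 effects and 1.34 (Cd8a) and 0.16 (mt-Nd3) for anti-CTLA4 in young mice. With only the libraries of the groups compared, 142 genes passed for anti-PD-L1 in young mice, 0 (571 at an unadjusted p under 0.05) for anti-CTLA4 in young mice and 2094 for age under anti-PD-L1. Gene estimates that turned were 0.08 (Cxcl9) for anti-CTLA4 in aged mice, 0.44 (Pdcd1) for anti-PD-L1 in aged mice and 0.10 (Ifng) for the difference of anti-PD-L1 effects. In the libraries of 1 batch, 138 genes passed for anti-PD-L1 in young mice, 0 (484 at an unadjusted p under 0.05) for anti-CTLA4 in young mice and 3596 for age under anti-CTLA4. There 7 lists passed for anti-CTLA4 in aged mice, 6 for the difference of anti-CTLA4 effects and 11 for the antibodies in young mice. The ribosomal median turned (0.43) for the difference of anti-PD-L1 effects. Both differences span batches. Genes turned with estimates of 0.02 (Cd8a), 0.01 (Cxcl9), 0.06 (Ifng) and 0.11 (Pdcd1) for anti-CTLA4 in aged mice, 0.44 (Pdcd1) for anti-PD-L1 in aged mice and 0.11 (Ifng) for the difference of anti-PD-L1 effects.

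With an estimated correlation, 2 lists passed for the antibodies in aged mice and 0 lists passed in the other comparisons. In the test of list levels, 5 lists passed for age under isotype and 11 for age under anti-PD-L1 and 0 lists passed in the others but age under anti-CTLA4. Without the 4 libraries of low TMM factor, 18 genes passed for anti-PD-L1 in young mice, 6 for anti-CTLA4 in young mice and 2690 for age under isotype. There 15 lists passed for anti-PD-L1 in young mice and 9 for anti-CTLA4 in aged mice. List tests that turned had medians of -0.04 (ribosomal) for anti-CTLA4 in young mice. Gene estimates that turned were 0.00 (Cd8a) and 0.20 (Cxcl9) for anti-CTLA4 in aged mice, 0.01 (Cxcl9) and 0.24 (Pdcd1) for anti-PD-L1 in aged mice and 0.02 (Ifng) for the difference of anti-PD-L1 effects. With the B cell list level as a covariate, 492 genes passed for anti-PD-L1 in young mice, 21 for anti-CTLA4 in young mice, 3 for anti-CTLA4 in aged mice, 4 for the antibodies in young mice and 2 for the antibodies in aged mice. There 8 lists passed for the antibodies in aged mice. List tests that turned had medians of -0.19 (cytotoxic), -0.13 (immunoglobulin) and -0.10 (lymph node) for the antibodies in aged mice. The B cell list, fixed near 0 by its own level, was not tested by this fit. Genes turned with estimates of 0.64 (Cd8a) for anti-CTLA4 in young mice. With the length trend as a covariate, 33 genes passed for anti-PD-L1 in young mice, 29 for anti-CTLA4 in young mice, 3439 for age under isotype, 2964 for age under anti-PD-L1 and 3 for the difference of anti-PD-L1 effects. There 10 lists passed for anti-PD-L1 in young mice, 13 for anti-PD-L1 in aged mice and 17 for anti-CTLA4 in aged mice. List tests that turned had medians of -0.11 (matrix), 0.06 (oxidative phosphorylation) and 0.07 (ribosomal) for anti-PD-L1 in aged mice, 0.14 (ribosomal) for age under anti-CTLA4, 0.16 (ribosomal) for the difference of anti-PD-L1 effects, 0.20 (ribosomal) for the difference of anti-CTLA4 effects and -0.08 (matrix) and -0.12 (ribosomal) for the antibodies in young mice. Gene estimates that turned were 0.16 (Cd8a), 0.25 (Cxcl9) and 0.14 (Pdcd1) for anti-CTLA4 in aged mice and 0.12 (Cxcl9) and 0.46 (Pdcd1) for anti-PD-L1 in aged mice.

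Without aged isotype replicate 7 the counts were 246 for anti-PD-L1 in young mice, 9 for anti-CTLA4 in young mice, 1432 for age under isotype, 819 for age under anti-PD-L1 and 5337 for age under anti-CTLA4, and the gene estimate that turned was 0.07 (Cd8a) for anti-CTLA4 in aged mice. The replicate block took the number that the labels give each library of a group, and these numbers did not pair the samples. Deviations from the group means of 2000 genes had a median correlation of -0.01 over 113 same-numbered pairs (-0.57 to 0.57, 37 over 0.1) and 0.01 over the others, and 7 of 52 libraries correlated best with their own number. With the block, 135 genes passed for anti-PD-L1 in young mice, 2 for anti-CTLA4 in young mice, 752 for age under isotype, 35 for age under anti-PD-L1 and 2 for the difference of anti-PD-L1 effects. There 7 lists passed for anti-CTLA4 in aged mice and 5 for the difference of anti-PD-L1 effects. Genes turned with estimates of -0.03 (Cd8a) for anti-PD-L1 in aged mice.

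Of the 276 gene results named in the text, those that kept their direction and side of the threshold numbered 276 with relative log expression factors, 237 with DESeq2, 257 with no filter, 234 with no batch term, 244 of 271 with only the groups compared, 160 of 183 with 1 batch, 247 with no library of low TMM factor, 265 with the B cell covariate, 255 with the length covariate, 270 with no aged isotype replicate 7 and 220 with the block. Genes that rose and fell with age under all 3 antibodies ran from 194 and 69 with no filter to 1280 and 682 with the length covariate over the settings but the block, where they were 13 and 14, and numbered 524 and 578 with no batch term, 222 and 154 with the B cell covariate and 575 and 381 with DESeq2. Libraries of 1 batch could not be had for age under isotype or anti-PD-L1 or for the differences of effects. With only the groups compared, the former had no batch term. Young isotype was shallowest (mean 14484226 counts), which limits precision of low genes there.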

Other observations

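The tests of explanations and of other splits in this part were chosen after the results were seen, while the comparisons of single genes were fixed before. Under anti-CTLA4, Slc12a2, an ion cotransporter, rose in aged mice from 28.5 ± 9.37 to 68.5 ± 20.7 CPM (1.42 ± 0.20, adjusted p = 3e-06), as did the exosome nuclease Dis3 (0.82 ± 0.11), the helicase Dhx36 (0.89 ± 0.12), Odf2l (0.99 ± 0.14) and Zfp808 (1.44 ± 0.20). Pde1a, a phosphodiesterase (-2.85 ± 0.36), Pla2g5 (-3.52 ± 0.44), Glipr2 (-1.49 ± 0.19), Gpsm3 (-0.91 ± 0.11) and Prr13 (-0.80 ± 0.10) fell, and adjusted p of the 10 genes was 3.38e-07 to 3e-06. They lay beyond the young median in 8 of the 8 aged libraries. Under anti-PD-L1, Exoc5, a subunit of the exocyst (1.07 ± 0.21, adjusted p = 0.00406), the deubiquitinase Atxn3 (0.98 ± 0.19), the small GTPase Rap2c (0.98 ± 0.19), the mitochondrial folate carrier Slc25a32 (0.78 ± 0.16) and Ubxn7 (0.73 ± 0.14) rose in aged mice. Car4, a membrane carbonic anhydrase, fell from 31.7 ± 17.7 to 3.31 ± 1.99 CPM (-3.45 ± 0.62, adjusted p = 0.00147), with Pde1a (-3.06 ± 0.55), Cacng7 (-2.71 ± 0.51), the prenyltransferase subunit Rabggta (-0.74 ± 0.14) and Mup16 (-7.08 ± 1.27), whose paralogs make its counts uncertain. Adjusted p of these 10 was 0.00147 to 0.00406, and they lay beyond the young median in 7 to 8 of the 8 aged libraries.

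Under isotype, the helicase Dhx32 (0.81 ± 0.14), Mpzl3 (1.22 ± 0.21), the centriole protein Cep83 (0.75 ± 0.13), Syap1 (0.85 ± 0.16) and the zinc finger genes Zfp869 (1.07 ± 0.19), Zfp955a (1.62 ± 0.30) and Zfp955b (1.69 ± 0.31), the last being close paralogs whose counts are uncertain, rose in aged mice. The acyl-CoA synthetase Acsf2 (-2.26 ± 0.39), the chromatin reader Brpf1 (-1.44 ± 0.25), Fry (-2.36 ± 0.42), the centriole protein C2cd3 (-1.97 ± 0.35) and the importin Ipo13 (-1.39 ± 0.25) fell, with adjusted p of 0.000577 to 0.00119 for the 12, which lay beyond the young median in 6 to 7 of the 7 aged libraries. In young mice, anti-PD-L1 went with higher Colec12, a scavenger receptor (0.77 ± 0.20), Ddah1, which degrades methylated arginines (1.01 ± 0.26), and Zfp790 (0.52 ± 0.13), and with lower Fry (-1.35 ± 0.26), Prr5l (-1.41 ± 0.26), the ATP synthase subunit Atp5g2 (-1.08 ± 0.20) and the pseudogene Rps12-ps5 (-2.61 ± 0.49), whose counts are uncertain. Adjusted p of these 7 was 0.00297 to 0.0343, and they lay beyond the isotype median in 9 to 10 of the 10 libraries.

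In fits of the isotype libraries alone and of the anti-PD-L1 libraries alone, where age and batch coincided, 1034 genes differed with age in the same direction in both, 602 higher and 432 lower. In the batch 1 libraries of anti-CTLA4, which took no part in choosing these genes and hold both ages, 1013 of 1015 tested genes (99.8%) had the same sign and 785 passed, which argues against sequencing batch as their whole source. The median log2 difference under isotype, taken in each gene's direction, was 0.72 with all libraries, 0.68 with the B cell list level and 0.71 with the length trend as a covariate, which argues against lymph node content and the trend in the same way. A difference that goes with the age of the mice is a candidate explanation, found and tested on the same series. Differences between ages in the source of the mice, in housing or in the lot of tumour cells stay open and untested, since the labels do not record them.

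Cytotoxic lymphocyte and interferon-gamma-induced genes were lower in aged than in young mice under anti-CTLA4, with level differences of -1.91 ± 0.36 and -1.12 ± 0.27 (log2, aged minus young). With the B cell list level as a covariate the differences were -1.79 ± 0.27 and -1.11 ± 0.28, which argues against differing lymph node content as the whole source, and with the length trend they were -1.71 ± 0.38 and -1.20 ± 0.29. Within batch 1, 4 young and 7 aged libraries differed by -1.8 (two-sided exact permutation p = 0.0121 over 330 splits, adjusted p = 0.0364 over 33 lists) and -1.12 (exact p = 0.00303, adjusted p = 0.0286). Relative to the mean of fibroblast and endothelial levels the cytotoxic level differed by -1.70 ± 0.36, so a larger share of tumour cells, which would lower all host cell types alike, could not be the whole source. Fewer or less active cytotoxic cells in aged tumours may account for the lower cytotoxic level and cannot be separated by these lists, and mouse source and tumour cell lot stay untested.

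Ribosomal and oxidative phosphorylation genes were lower than under isotype with anti-PD-L1 at both ages and with anti-CTLA4 in aged mice, by list tests that did not hold (smallest adjusted p = 0.83, 0.993 and 0.978 with an estimated correlation), and a candidate explanation is the length trend of the libraries, such as differing RNA quality would give. With the trend as a covariate, genes with unadjusted p under 0.05 went from 4339 to 1070 for anti-PD-L1 in young mice, from 5379 to 366 in aged mice and from 5321 to 215 for anti-CTLA4 in aged mice, where 895 are expected with no difference. For anti-CTLA4 in young mice, where the ribosomal list passed and oxidative phosphorylation did not, the trend differed by 0.037 ± 0.113, the ribosomal level by -0.34 ± 0.33 without and -0.24 ± 0.14 with the covariate, its list median was -0.04 without the 4 libraries of low TMM factor, and the genes went from 1247 to 1758, so the trend is not offered as an explanation there. Without these libraries the first 3 counts were 1225, 4357 and 4308. These libraries bear on the young mice and do not account for the aged ones. Fewer samples are left, and the limits for such counts were set with these seen. The trend differed in the first 3 comparisons, so the covariate may also remove an antibody effect that follows gene length. Technical and biological sources stay open.

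The labels of the libraries in each comparison were redrawn 99 times and refitted, and the real split is counted among the 100. No other split reached the real count for age under anti-CTLA4, where 1 of 100 splits, the real one, gave at least the 5485 real genes and the highest other 203. It was also excluded for age under anti-PD-L1, where 1 of 100 splits gave at least the 903 real genes and the highest other 320. For anti-CTLA4 in young mice 2 of 100 splits gave at least the 13 real genes and the highest other 937, though the next split had 12, a margin of 1 gene. With that margin the count does not exclude chance there. The redraws did not keep the batches, and isotype there came from batch 2 alone. In that comparison edgeR called 0 genes within batch 2 and 0 with only the groups compared. Chance was not excluded for age under isotype, where 5 of 100 splits gave at least the 1505 real genes and the highest other 4004. Nor was it for anti-PD-L1 in young mice, where 13 of 100 splits gave at least the 285 real genes and the highest other 5741. Other splits of these 2 and of the young anti-CTLA4 comparison called several times the real count, which points to a structure of the samples beyond the groups. The 4 splits of the isotype libraries with as many genes each differed by at least 0.179 in mean length trend (log2 CPM per doubling of length), against 0.042 between the ages, and under anti-CTLA4 the ages differed by 0.183. The 12 of the young anti-PD-L1 and isotype libraries differed by as little as 0.06, under the median of the other splits (0.081), and the highest by -0.283, against 0.209 for the real one, so not all of them followed the trend. Under isotype and under anti-PD-L1 the real split of the ages also follows the sequencing batches, since no batch held both ages, so no value within a batch can be had and batch stays open by this count.

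In the other comparisons edgeR called 0 genes, so 100 of 100 splits gave as many. Genes with unadjusted p under 0.05 in the real and highest other split numbered 5379 and 4959 for anti-PD-L1 in aged mice. They numbered 5321 and 5697 for anti-CTLA4 in aged mice, 655 and 4276 for the difference of anti-PD-L1 effects and 1257 and 7261 for anti-CTLA4. For the antibodies they numbered 1242 and 4972 in young and 243 and 2704 in aged mice. The real split led only for anti-PD-L1 in aged mice. Other splits called at most 23, 1, 4, 4831, 904 and 9 in turn.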
